A study of Mus musculus with 6 samples.

How the data were processed

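Tagmentation-based whole-genome bisulfite sequencing was measured in 6 samples of genomic DNA from BALB/c mice. Per the labels, 3 pCAF samples are PDPN-positive, Ter119-, CD45- and EpCAM-negative cells of tumours grown after injection of 100000 4T1-luc cells into the mammary fat pad, and 3 NMF samples are normal mammary fat pad cells passed through the same negative gates without PDPN selection. The selection label of pCAF replicate 3 alone reads PDPN-negative. DNA was tagmented with Tn5 transposase, treated with bisulfite and split into 4 barcoded libraries per sample, which were sequenced as paired ends on an Illumina HiSeq2000, per the labels. The submitters' processing notes name Trimmomatic 0.36, BWA 0.7.8, Picard and MethylDackel 0.3.0 and the mouse build mm10. Their settings, the joining of the libraries, the conversion rate of the phage λ spike and any coverage filter are not given in the sources used here.

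The deposited tables give, for each CpG and sample, a fraction between 0 and 1, the share of methylated calls made by the authors. The 2 tables hold the same positions, the same missing cells and the same fractions to within 1.0e-15, so no read counts stand beside the values and read depth per CpG is unknown. Of 21867550 CpGs, 88.5%, 87.8% and 89.8% had a value in pCAF replicates 1 to 3 and 90.4%, 89.3% and 89.5% in NMF replicates 1 to 3, and 1724323 had a value in no sample. Between 11.8% and 16.3% of a sample's values were exactly 0 and 25.9% to 36.6% exactly 1. Without depth, the precision of a single CpG cannot be given. The spread between the 3 samples of a group is the only error used.

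Samples were grouped by their titles. Differences are pCAF minus NMF in percentage points. The test fixed before the data were examined, a quasi-binomial model of read counts, needs counts and was replaced by limma 3.58.1 in R 4.3.3 on logit levels, fixed at that time as its alternative: log2((m + 0.05)/(1 - m + 0.05)) with m the mean fraction of a region's CpGs. Variances were moderated with a trend on the log2 number of CpGs, and p-values were adjusted by Benjamini-Hochberg over all regions of a kind. A region was called where the adjusted p was under 0.05 and the difference of group means at least 20 points. Regions used CpGs with a value in all 6 samples and needed at least 3 CpGs. They were windows of 1 kb (500 bases and 5 kb as alternatives), gene ends and low-methylated elements. Single CpGs were tested with the same moderated test written in numpy and checked against limma on a sample of CpGs. Single values per sample, such as mean levels, were compared by a two-sided exact permutation test, whose smallest p with 3 against 3 samples is 0.1. Other work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. The fits were tested on simulated data, the mean levels of the real regions with noise drawn from their residual spread, with 200 regions each changed by 20, 30 and 40 points.

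Low-methylated elements were added after the data had been examined, because windows of 1 kb gave no calls. They are runs of at least 8 CpGs, no gap over 500 bp, whose mean over all 6 samples, smoothed over 2 CpGs on each side, is under 60%. The group of a sample played no part in their choice. Gene coordinates came from a RefSeq table of the same coordinates as mm10 without strand, so both ends of each gene (1000 bases outside to 500 inside) replaced promoters, and for list tests at gene ends the CpG-richer end of each gene was taken, which had the lower level in 73.5% of 30967 genes. CpG-dense windows have at least 30 CpGs per kb. No genome sequence was at hand, so motif density, CpG islands by sequence and the flanking bases of solo CpGs were not analysed here.

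The 23 gene lists were fixed before the data were examined: pan-fibroblast, myofibroblastic CAF, inflammatory CAF, antigen presentation, resident adventitial fibroblast, adipocyte, endothelial, pericyte and smooth muscle, epithelial, leukocyte, Schwann and neural crest, RUNX family and partner, TGF-β pathway, extracellular matrix remodelling, Wnt and Hedgehog signalling, Hox, other developmental transcription factors, interferon response, hypoxia and glycolysis, cell cycle, DNA methylation machinery, imprinted and germline genes. Of 603 list symbols, 600 were matched by symbol, 1 by an older symbol and 2 (Mx1 and Mx2) not at all. Saa3 alone stands in 2 of these lists. For each list, the number of genes with a called element in the gene or within 5 kb was compared with 10000 random lists of genes with the same numbers of tested elements, one-sided, adjusted over the 46 tests of 23 lists by 2 directions (seed 11). Elements took the place of windows in this test after the data had been examined. The list levels were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, at the CpG-richer gene ends and, added after the data had been examined, at elements. Members were also adjusted over the list alone.

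Genes were named by a rule fixed before the data were examined: Runx1, Runx2, Runx3, Cbfb, Pdpn, Epcam, Ptprc and Acta2 whatever their values, and up to 8 gene ends per direction of largest difference past both thresholds without predicted genes. From each list the rule took up to 2 gene ends of smallest adjusted p past both thresholds and up to 2 genes with the most called windows. The part of the rule on merged windows gave none, and the 10 genes per direction with the most called elements were taken instead, after the data had been examined. Elements also took the place of windows for list members, which were ranked by the number of called elements and then by the size of the mean difference.

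Alternatives covered the size threshold (10 and 30 points), the offset (0.01 and 0.1), untransformed levels, the variance trend, variances of each region alone, centring on the median region, a replicate block by sample number, autosomes, the number of CpGs (10 and 20), narrower and wider gene ends, element limits (50% and 40%, 5 CpGs), unmatched random lists, protein-coding genes, and each sample left out in turn.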

Results

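Whole-genome bisulfite sequencing compared PDPN-positive fibroblasts sorted from orthotopic 4T1 mammary tumours (pCAF, n = 3) with non-immune, non-epithelial stromal cells of the normal mammary fat pad (NMF, n = 3) of BALB/c mice. The series title links the methylome of cancer-associated fibroblasts to RUNX1, so the RUNX genes were fixed among the genes to be reported. The 2 sorts differ by more than the tumour: NMF were collected without PDPN selection, the age labels read 12 weeks for NMF and 8 weeks for pCAF, and libraries started from 25 ng of DNA for NMF and 8.5 ng for pCAF. The 8 weeks are also the age given for tumour cell injection and the design text calls the mice age matched, so whether age differed at collection is not known. The selection label of pCAF replicate 3 reads PDPN-negative while its source reads PDPN-positive, so each leading count is also given without it. Of 21867550 CpGs listed, 18187493 (83.2%) had a value in all 6 samples. Read depth behind each value is unknown.

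The pCAF methylome was slightly less methylated than the NMF methylome, mostly in bodies of genes, between genes and on the X chromosome, while the groups differed by under 1 point in CpG-dense DNA. Mean CpG methylation was 65.9 ± 0.361% in pCAF and 67.6 ± 0.591% in NMF (mean ± SD, n = 3 per group), a difference of -1.75 points, with all 3 pCAF samples below all 3 NMF samples. The difference was -1.58 points inside genes, -2.30 points between genes and -2.34 points at solo CpGs, which have no other CpG within 35 bases. On the X chromosome the level was 65.6 ± 0.617% in pCAF and 68.9 ± 1.03% in NMF (-3.32 points), against -1.68 points on the autosomes, where chromosomes 19 (-1.33 points) and 7 (-1.92 points) marked the ends of the range. Within 1 kb of gene ends the levels were 35.3% and 35.8% (-0.514 points, exact p = 0.2), and in CpG-dense windows 18.7% and 18.6% (0.182 points, exact p = 0.4). The genome-wide, gene-body, intergenic, solo and X differences each gave p = 0.1 in a two-sided exact permutation test, the smallest p that 3 against 3 samples can give, so none can pass a threshold of 0.05.

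**Figure D1:**
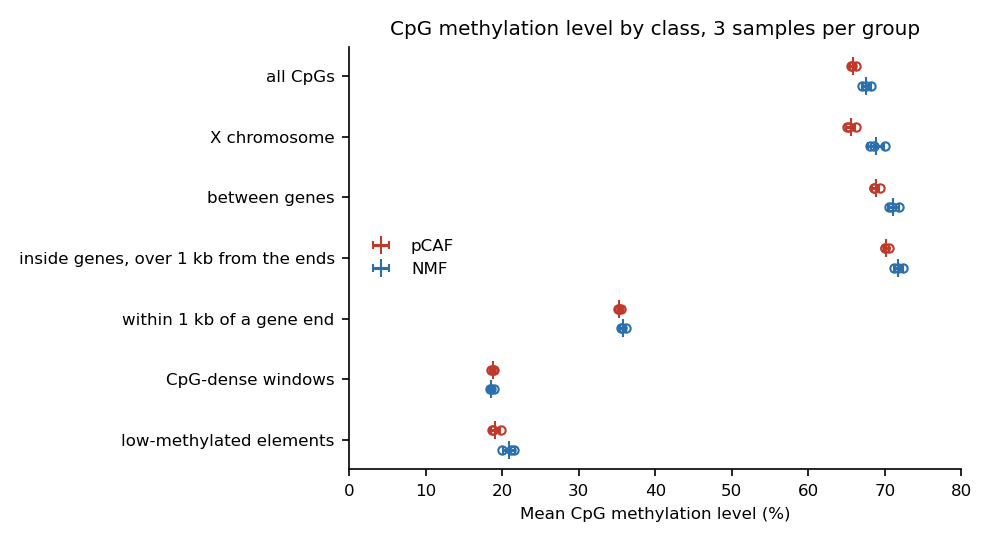
Mean CpG methylation level (%) by class of CpG in pCAF and NMF. Open circles are single samples (n = 3 per group) and ticks with bars are the group mean ± SD.

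Differences were then tested in short stretches of low or intermediate methylation, the kind of DNA that holds promoters and enhancers. As a class these low-methylated elements differed about as much (-1.77 points) as the DNA outside them (-1.74 points, exact p = 0.1 each, the smallest possible). Of 131383 elements, 3257 fell and 487 rose in pCAF (limma, adjusted p under 0.05 and a difference of at least 20 points). With variances of each element alone, not moderated across elements, the same test called 0 in either direction (4492 higher and 17291 lower at an unadjusted p under 0.05). The elements that fell had a median level of 47.4% in NMF and 21.1% in pCAF, and those that rose 29.8% in NMF and 55.6% in pCAF. They were short, with median lengths of 787 bp (lower) and 576 bp (higher) and a median of 11 CpGs each. Elements with a mean level under 5%, mostly unmethylated in both groups, differed by -0.102 points (exact p = 0.4), whereas those of 20 to 30% differed by -5.02 points (exact p = 0.1, the smallest possible). The groups did not overlap at 25.6% of all tested elements, where chance gives 10%. The 100% of the lower and 99.8% of the higher elements without overlap follow largely from the calling thresholds. The median over all tested elements was -2.24 points, and with each sample centred on its median the counts were 712 higher and 2099 lower. The counts depended on single samples: without pCAF replicate 3 they were 83 higher and 830 lower, without pCAF replicate 2 143 and 1296, without NMF replicate 1 38 and 454, and without NMF replicate 3 72 and 704. At 23 higher and 345 lower elements the call held with all 6 samples and with each one left out, and these are called stable below, a term that covers left-out samples only. Examples beyond the genes that the naming rule gives were chosen after their values were seen, with stable elements preferred. Elements were defined, without regard to group, after the data had been examined.

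Elements lower in pCAF lay more often inside genes and less often near gene ends than tested elements did. Of the lower elements, 56.4% lay inside a gene over 1 kb from its ends (44.3% of tested, Fisher adjusted p = 7.13e-44) and 7.86% within 1 kb of a gene end (18.8% of tested, adjusted p = 1.61e-70). CpG-dense elements made up 6.29% of the lower elements and 21.6% of the higher ones, against 15.1% of those tested (adjusted p = 4.79e-55 and 0.000269). Elements inside genes also made up 50.9% of the higher elements (adjusted p = 0.00658), and those between genes 31.8% of them against 36.8% of tested (adjusted p = 0.0297). Between genes the lower elements made up 35.7% (adjusted p = 0.22). The X chromosome held 0.616% of the higher and 0.399% of the lower elements, against 2.06% of those tested (adjusted p = 0.0231 and 1.15e-15). When the background was restricted to elements with an NMF level of at least 50%, the ratio for lower elements near gene ends moved from 0.417 to 0.928 and that for CpG-dense ones from 0.417 to 1.07. Neighbouring elements are not independent, so these p-values overstate the evidence.

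Runx1 and Runx2, transcription factors of the runt family, lost methylation at elements inside their gene bodies. Runx2 fell from 35.9 ± 6.76% in NMF to 8.62 ± 1.70% in pCAF at a stable element on chromosome 17 (44500213 to 44500984, -27.2 points, adjusted p = 0.0068, lower in 3 of 3 pCAF samples). At Runx1, 4 of 28 elements fell, among them chromosome 16, 92620749 to 92622267, from 55.7 ± 3.83% to 30.6 ± 4.65% (-25.0 points, adjusted p = 0.013). A second Runx1 element, 92717967 to 92718265, fell from 63.6 ± 3.06% to 34.9 ± 3.26% (-28.7 points, adjusted p = 0.017). The CpG-richest Runx1 element, with 280 CpGs, stood at 5.92 ± 0.446% in pCAF and 6.47 ± 0.431% in NMF (adjusted p = 0.62). A Runx1 element of 60 CpGs was higher in pCAF, at 26.0 ± 7.06% against 10.9 ± 2.41%, and its 15.1 points were under the size threshold (adjusted p = 0.019). These last 2 Runx1 elements and the second were chosen after their values were seen.

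Runx3 had 0 of 12 elements called and Cbfb, which encodes the shared partner subunit, 0 of 5 with limma. The Runx3 element of smallest adjusted p differed by 4.19 points (adjusted p = 0.059) and that of Cbfb by -9.73 points (adjusted p = 0.44). Over the RUNX list 6 of 70 elements fell, also when adjusted over the list alone. Lower elements were found at 2 of the 4 genes, where 10000 random lists matched on the number of elements held 1.47 on average (adjusted p = 1). Leaving out pCAF replicate 3 left 2 of the 70 elements lower, at 2 genes (adjusted p = 0.627). The first Runx1 element lost its call without NMF replicate 1 (adjusted p = 0.064) or NMF replicate 3 (0.059), and the second without pCAF replicate 3 (0.064), NMF replicate 1 (0.072) or NMF replicate 3 (0.07).

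**Figure D2:**
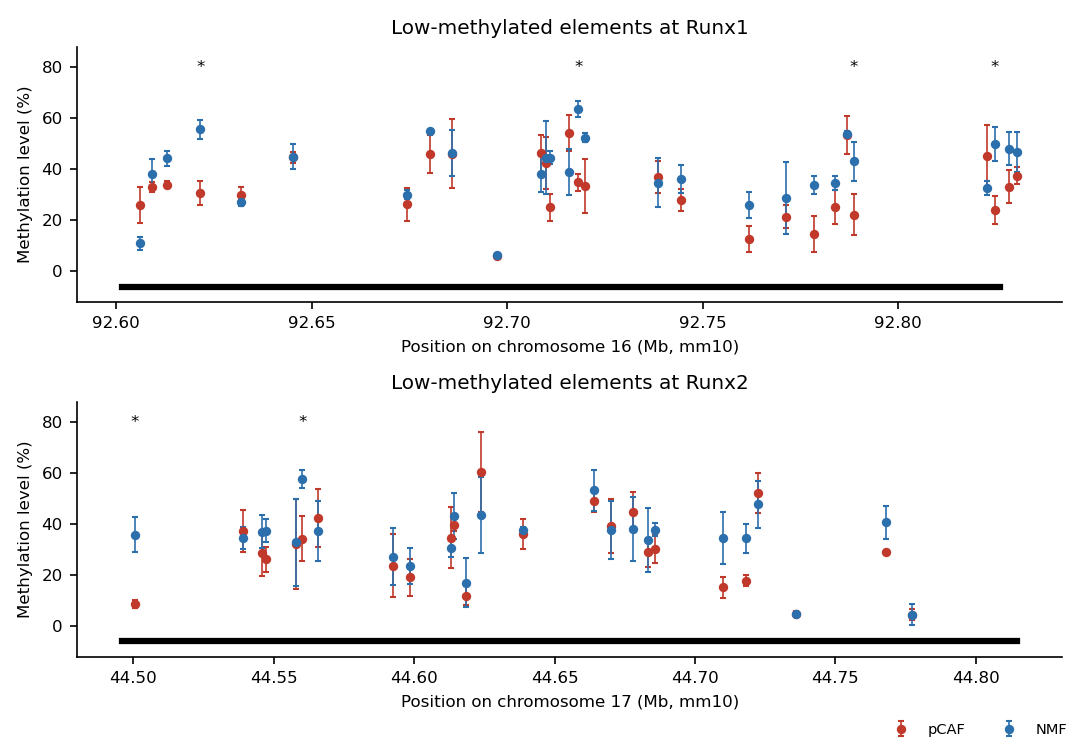
Methylation level (%) of the low-methylated elements along Runx1 and Runx2 by genomic position, as mean ± SD of 3 samples per group. Asterisks mark called elements and black bars the genes.

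Genes of the TGF-β pathway carried lower elements more often than matched random genes. Of 28 genes, 11 held at least 1 lower element against 4.95 on average in 10000 matched random lists (adjusted p = 0.0368), and 22 of 262 elements fell while 1 rose (30 and 1 when adjusted over the list alone). Smad3, the signal transducer of the pathway, fell from 64.4 ± 5.05% to 12.6 ± 2.33% at a stable element on chromosome 9 (63743834 to 63744159, -51.8 points, adjusted p = 0.0028), and a second stable Smad3 element fell from 30.8% to 4.90%. Stable elements also fell in Tgfb2, a ligand (57.0 ± 6.85% to 24.1 ± 1.66%, -32.8 points, adjusted p = 0.0082), and in Ltbp1, which binds latent TGF-β (48.4 ± 2.88% to 15.1 ± 7.12%, -33.3 points, adjusted p = 0.0089). Lower elements lay among others at Tgfbr2 (3), Tgfbr3 (3), Bmp1 (3), Smad6 (2), Acvr1, Bmpr1a and Ltbp2, and 1 higher element near Bmp4. Without pCAF replicate 3, 7 elements at 5 genes were lower and 0 higher. Across the elements of the list, camera with its preset correlation gave a shift down (adjusted p = 0.00175, median -4.87 points; adjusted p = 0.375 with an estimated correlation). The excess over random lists was lost with the replicate block (adjusted p = 0.0966), after centring (0.0598), at 30 points (0.793) and without any 1 sample other than pCAF replicate 2: 0.301 without pCAF replicate 1, 0.27 without pCAF replicate 3, 1 without NMF replicate 1, 0.0635 without NMF replicate 2 and 0.463 without NMF replicate 3. Beside this, pCAF were selected for PDPN and NMF were not. Gene ends of markers of endothelial cells, which the NMF sort did not exclude, were higher in pCAF (mean 4.38 points). Whether the lower TGF-β elements come from different sorted cells was not tested, and their opposite direction does not decide it.

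**Figure D3:**
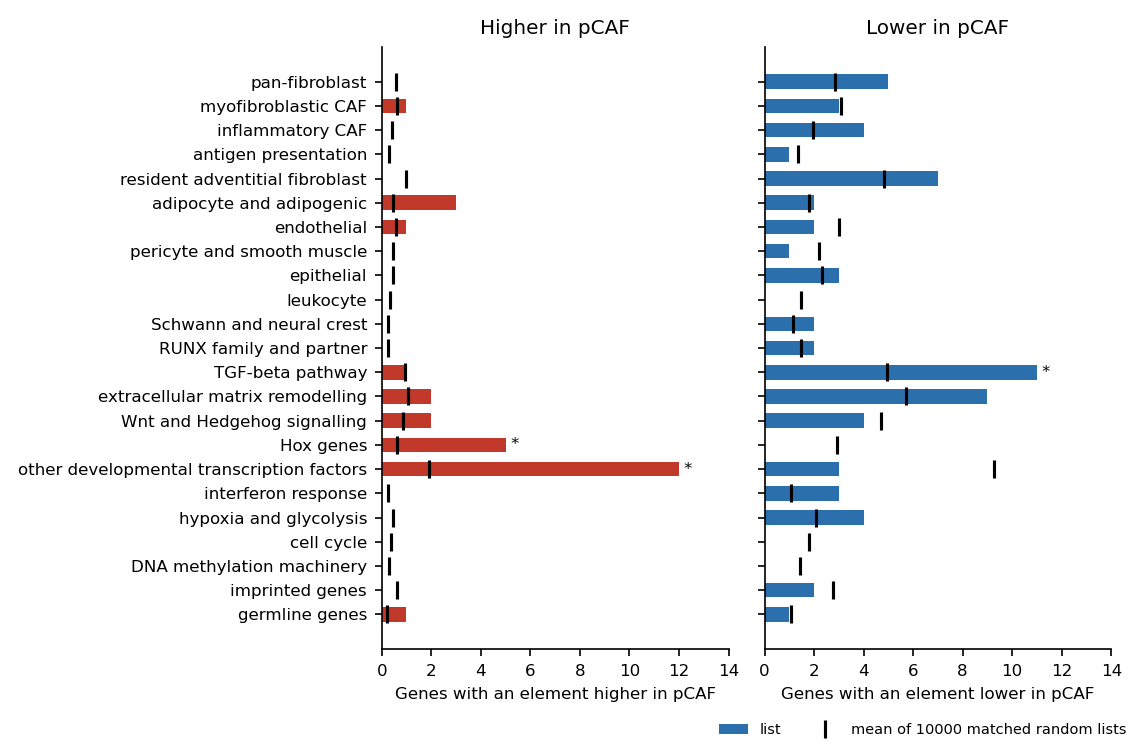
Number of genes per list with at least 1 element called higher or lower in pCAF (bars) and the mean of 10000 matched random lists (black ticks). Asterisks mark an adjusted p under 0.05 over the 46 list tests. An element shared by neighbouring Hox genes counts for each of them, which the random lists do not mimic.

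Fibroblast genes also carried lower elements, among them the genes of sort and lineage markers. Pdpn, the marker used to sort pCAF, fell from 28.6 ± 5.16% to 5.74 ± 0.930% at a stable element inside the gene (chromosome 4, 143288141 to 143289458, -22.8 points, adjusted p = 0.0068). Lower elements in the pan-fibroblast list were 6 of 138 (8 adjusted over the list alone), at Pdpn, Col3a1, Fn1, Ddr2 and Col1a2. Camera gave a shift down at its elements (adjusted p = 3.93e-05, median -8.23 points; adjusted p = 0.458 with an estimated correlation), while 5 of 20 genes with a lower element against 2.85 expected gave adjusted p = 0.699. Only 1 element, at 1 gene, was lower without pCAF replicate 3 (adjusted p = 1). Beside this, pCAF were selected for PDPN and NMF were not, and the endothelial gene ends were higher in pCAF by 4.38 points on average.

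In the list of resident adventitial fibroblasts, 18 of 285 elements fell and 0 rose with limma (29 and 1 adjusted over the list alone), at 7 of 20 genes against 4.82 in random lists (adjusted p = 0.713). Dpp4, a surface peptidase of this cell type, fell from 55.5 ± 6.45% to 24.0 ± 1.19% at a stable element (-31.5 points, adjusted p = 0.0091), and Fbn1, the gene of fibrillin 1, from 52.0 ± 7.64% to 22.8 ± 2.77% (-29.2 points, adjusted p = 0.009, stable). Fbn1 had 8 of 49 and Dpp4 4 of 12 elements called, and the others lay at Sema3c, Ebf1, Col14a1, Smoc2 and Pi16. Camera gave a shift down at elements (adjusted p = 0.00011, median -8.35 points; adjusted p = 0.458 with an estimated correlation). When pCAF replicate 3 was left out, 6 elements at 3 genes were lower (adjusted p = 0.95) and 1 was higher. The PDPN selection and the endothelial gene ends (4.38 points) stand beside this list too.

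Inflammatory fibroblast genes had 5 of 106 elements lower and 0 higher (10 and 0 adjusted over the list alone), at 4 of 26 genes against 1.95 (adjusted p = 0.699), with a shift down by camera (adjusted p = 0.00173, median -6.10 points; adjusted p = 0.0966 with an estimated correlation). Has1, a hyaluronan synthase, fell at a stable element from 45.04 ± 4.54% to 13.5 ± 2.63% (-31.5 points, adjusted p = 0.0077), and Il33, an alarmin cytokine, from 31.9 ± 5.30% to 8.99 ± 2.46% over 52 CpGs (-22.9 points, adjusted p = 0.0054). Without NMF replicate 1 the Il33 difference was -19.9 points, under the size threshold. Cxcl12 and Il1r1 held the other lower elements. The lower elements numbered 4 without pCAF replicate 3, at 4 genes against 0.579 in random lists (adjusted p = 0.0414; 0.103 to 1 without any other sample). Beside these values as well, the sorts differed in PDPN and endothelial gene ends were higher by 4.38 points. Slpi, a secreted protease inhibitor in the antigen presentation list, fell from 62.2 ± 4.79% to 24.9 ± 7.33% (-37.3 points, adjusted p = 0.0089, stable) and was the only gene of that list with a called element, 1 of 71 in total (1 also adjusted over the list alone; 1 gene against 1.34, adjusted p = 1; without pCAF replicate 3, 2 elements at 2 genes, adjusted p = 0.582).

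Myofibroblast genes did not exceed random lists: 5 elements fell and 1 rose of 150 (7 and 1 adjusted over the list alone), at 3 of 24 genes against 3.10 (adjusted p = 1), at Col8a1 (3), Itgb5 and Actn1, and without pCAF replicate 3 4 fell and 0 rose. Col8a1 fell from 69.8 ± 2.15% to 25.3 ± 12.2% at its element of largest difference (-44.5 points, adjusted p = 0.01; 0.051 without NMF replicate 1). Acta2, the smooth muscle actin of myofibroblasts, had no called element with limma, and the one of smallest adjusted p differed by -8.37 points (adjusted p = 0.11).

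In extracellular matrix remodelling, 12 elements fell and 2 rose of 283 (16 and 4 adjusted over the list alone), with 9 of 33 genes holding a lower element against 5.73 (adjusted p = 0.699). The counts without pCAF replicate 3 were 2, at 1 gene, and 0. Adamts2, which trims procollagen, fell at 2 stable elements, from 59.8 ± 12.5% to 17.5 ± 4.97% and from 46.1 ± 4.18% to 21.7 ± 2.23% (adjusted p = 0.0092 and 0.0091). The 2 higher elements lay at Col4a1 and Col4a2, which encode basement membrane collagen. The Col4a2 element rose from 29.2 ± 6.82% to 55.5 ± 3.10% (26.2 points, adjusted p = 0.017), a call lost without pCAF replicate 2 (adjusted p = 0.06), pCAF replicate 3 (0.056) or NMF replicate 1 (0.073).

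Signalling lists gave scattered calls. Wnt and Hedgehog genes had 6 lower and 2 higher of 241 elements (8 and 2 adjusted over the list alone; 4 genes against 4.70, adjusted p = 1, and 2 against 0.876, adjusted p = 0.823), lower at Gli2, Tcf7l1, Wnt5b and Dkk3 and higher at Rspo3 and Wif1. Hypoxia and glycolysis genes had 7 of 111 lower (7 adjusted over the list alone; 4 genes against 2.07, adjusted p = 0.699), at Hk2 (3), Hif1a (2), Car12 and Pfkp. Hk2, a hexokinase, fell from 41.2 ± 4.94% to 16.1 ± 3.02% (-25.1 points, adjusted p = 0.0079, stable). Interferon response genes had 3 of 64 lower (3 adjusted over the list alone; 3 genes against 1.08, adjusted p = 0.699), among them elements at Cxcl9 and Bst2. The Wnt and Hedgehog list had 1 higher and 0 lower without pCAF replicate 3, and the hypoxia and interferon lists 1 lower each.

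Genes of developmental transcription factors carried higher elements more often than matched random genes. Of 77 such genes outside the Hox clusters, 12 held a higher element against 1.92 in matched random lists (adjusted p = 0.0046), with 17 of 525 elements higher and 4 lower (21 and 9 adjusted over the list alone). Of 104 further developmental factors, listed once this result was known, 1 held a higher element against 1.27 in random lists (permutation p = 0.725) and 4 a lower one. Irx3, a homeobox factor, rose from 15.4 ± 2.34% to 45.8 ± 8.85% over 125 CpGs next to the gene (chromosome 8, 91803906 to 91807042, 30.4 points, adjusted p = 0.0054). Tbx15 rose from 19.9 ± 1.35% to 46.6 ± 6.90% (26.7 points, adjusted p = 0.0054), Tbx4 from 19.3 ± 3.67% to 47.1 ± 6.79% (27.8 points, adjusted p = 0.0059) and Hand1 from 21.1 ± 5.91% to 48.4 ± 2.06% (27.4 points, adjusted p = 0.0071). En1 rose by 26.0 points and Gata3 by 24.5 points, and all 6 of these elements were stable. Other higher genes included Alx4, Pitx1, Sox9, Gata4 and Emx2, and lower elements lay at Prrx1, Wt1 and Foxp1. At Foxp1 a stable element fell from 57.6 ± 12.4% to 6.54 ± 2.69% (-51.0 points, adjusted p = 0.0054). Without pCAF replicate 3, 9 elements were higher and 5 lower, with 7 genes holding a higher one against 0.391 (adjusted p = 0.0046). The higher elements numbered 10, at 8 genes, without pCAF replicate 2, 8, at 7 genes, without NMF replicate 1 and 8, at 6 genes, without NMF replicate 3 (adjusted p = 0.0023, 0.0046 and 0.0046). Endothelial gene ends moved in the same direction as this list (mean 4.38 points).

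Hox genes, which set position along the body axis, showed the same direction on fewer elements: 3 of 88 rose and 0 fell with limma (4 and 0 adjusted over the list alone), 1 of them shared by Hoxb7, Hoxb8 and Hoxb9. This made 5 of 39 genes against 0.630 in random lists (adjusted p = 0.0069), an excess lost without the flank of 5 kb (adjusted p = 0.322), at 30 points (1), without pCAF replicate 3 (1 gene and 1 element, 0.913), NMF replicate 1 (1) or NMF replicate 3 (0.81). The random lists drew each gene singly from the whole genome, so they seldom hold neighbours that share an element. The adjusted p of 0.0069 therefore overstates the evidence for clustered genes. The Hoxb8 element rose from 31.1 ± 8.38% to 60.8 ± 9.74% (29.7 points, adjusted p = 0.025; lost without pCAF replicate 3, 0.075, NMF replicate 1, 0.1, or NMF replicate 3, 0.057). The Hoxc4 element rose from 19.2 ± 2.76% to 39.4 ± 5.74% (20.2 points, adjusted p = 0.0075; 16.95 points without pCAF replicate 2 and 18.7 without NMF replicate 1), and the third lay near Hoxc11. Adjusted over the list alone, 6 of 78 Hox gene ends were higher (Hoxc4, Hoxc5, Hoxc11, Hoxc12, Hoxc13 and Hoxa11) and 2 lower (Hoxa9, -25.3 points, and Hoxc9, -22.2 points), with 0 called over all gene ends. Endothelial gene ends moved in this direction too (mean 4.38 points).

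As groups, both lists shifted up, as did the endothelial list. By camera at the CpG-richer gene ends, the developmental factors had adjusted p = 3.93e-07 (median 1.40 points; adjusted p = 0.164 with an estimated correlation) and the Hox genes adjusted p = 0.00653 (median 0.854 points; adjusted p = 0.417 with an estimated correlation; 0.275 without pCAF replicate 3). At elements the values were 7.22e-06 (median 0.726 points; adjusted p = 0.0821 with an estimated correlation) and 4.72e-09 (median 2.34 points; adjusted p = 0.094 with an estimated correlation). Adjusted over the list alone, 6 of 154 gene ends of the developmental factors were higher, among them those of Msx2, Hand1, Pitx1, Emx2 and En1, and 1 was lower, that of Wt1 (-28.6 points).

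Markers of endothelial cells, which the NMF gate did not exclude, were more methylated at their gene ends in pCAF. By camera the CpG-richer ends of 22 endothelial genes shifted up (adjusted p = 1.91e-05, mean 4.38 and median 2.42 points; adjusted p = 0.164 with an estimated correlation), and 18 of the 22 differences were above 0. The end of Tie1, an endothelial receptor kinase, stood at 80.9 ± 1.55% in pCAF and 65.6 ± 7.12% in NMF (adjusted p = 0.18), that of Cdh5, the endothelial cadherin, at 70.4 ± 7.18% and 61.2 ± 2.71% (adjusted p = 0.45), and that of Cldn5 at 36.3 ± 2.5% and 28.4 ± 2.88% (adjusted p = 0.3), whereas Pecam1 stood at 84.1 ± 4.81% and 86.4 ± 1.91% (adjusted p = 0.82). Esam was the 1 end of 44 called when adjusted over the list alone (20.3 points, adjusted p = 0.031), with 0 called over all ends. At elements camera also gave a shift up (adjusted p = 0.00011, median 1.94 points; adjusted p = 0.094 with an estimated correlation), with 1 element higher (Erg) and 2 lower (Erg and Cdh5) of 145 (0 and 1 adjusted over the list alone; 1 gene against 0.574 and 2 against 3.02, adjusted p = 1 each; without pCAF replicate 3 1 higher and 0 lower). The genes named here by level were chosen after their values were seen.

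Pericytes, smooth muscle and Schwann cells, which the NMF gate did not exclude either, and epithelial cells and leukocytes, which both gates were set to remove, gave few calls. Pericyte and smooth muscle genes had 2 of 113 elements lower, both at Synpo2 (2 adjusted over the list alone; 1 gene against 2.20, adjusted p = 1), with a mean gene-end difference of -0.0425 points. Epithelial genes had 3 of 125 lower, at Epcam, Ovol2 and Cdh3 (2 adjusted over the list alone; 3 genes against 2.34, adjusted p = 1). Cdh3, the P-cadherin, fell from 52.3 ± 1.59% to 13.0 ± 1.05% (-39.4 points, adjusted p = 0.0051, stable). Epcam, the marker of the negative gate, fell from 56.2 ± 2.91% to 30.4 ± 9.62% at an element 287 bases outside the gene (adjusted p = 0.034), a call lost without pCAF replicate 2 (0.099), pCAF replicate 3 (0.098), NMF replicate 1 (0.12), NMF replicate 2 (0.052) or NMF replicate 3 (0.12). Leukocyte genes had 0 of 83 called with limma (0 adjusted over the list alone; random mean 1.47 lower, adjusted p = 1), and Ptprc, the gene of CD45, differed by -12.2 points at its element of smallest adjusted p (0.34). Schwann and neural crest genes had 2 of 60 lower, at Cnp and Mbp (2 adjusted over the list alone; 2 genes against 1.15, adjusted p = 1). The pericyte, epithelial and Schwann lists had 1 lower element each without pCAF replicate 3 and the leukocyte list 0 with limma.

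Adipocyte and adipogenic genes had 3 of 118 elements higher, at Fabp4, Cd36 and Pnpla2, and 2 lower, at Pparg and Cidea (5 and 4 adjusted over the list alone). The 3 genes with a higher element compared with 0.449 in random lists (adjusted p = 0.116; 4 genes and 0.023 without NMF replicate 2), and the 2 with a lower one with 1.81 (adjusted p = 1). Without pCAF replicate 3 limma called 0 elements of the list. Fabp4, the fatty acid carrier of fat cells, rose from 23.5 ± 5.24% to 47.6 ± 4.72% (24.1 points, adjusted p = 0.03), a call kept only without NMF replicate 2 (0.033) and lost without pCAF replicate 1 (0.053), pCAF replicate 2 (0.059), pCAF replicate 3 (0.092), NMF replicate 1 (0.13) or NMF replicate 3 (0.096).

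Genes of cell division and of methylation itself were not called. Cell cycle genes had 0 of 100 and genes of the DNA methylation machinery 0 of 77 elements called with limma, also adjusted over each list alone (random means 1.79 and 1.45 lower, adjusted p = 1 each). Camera gave the cell cycle list a shift up relative to other elements (adjusted p = 0.0272; mean -0.392 and median 0.0641 points, of opposite sign; adjusted p = 0.206 with an estimated correlation), lost without NMF replicate 1 (0.0651) or pCAF replicate 2 (0.0601). Imprinted genes had 2 of 136 lower, at Mcts2 and Airn (2 adjusted over the list alone; 2 genes against 2.76, adjusted p = 1). Germline genes had 1 higher, at Asz1, and 1 lower, at Tdrd1, of 60 (1 and 1 adjusted over the list alone; 1 gene against 0.207, adjusted p = 0.794, and 1 against 1.07, adjusted p = 1). In each of these 4 lists limma called 0 elements without pCAF replicate 3.

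Genes with many lower elements, ranked after the data had been examined, included Creb5 (9), Fbn1 (8), Lrmda (7), Pmepa1, Disp1, Slit3, Rbms3 and Babam2 (6 each) and Auh (5). Pmepa1, an inhibitor of TGF-β signalling, fell at a stable element from 54.8 ± 11.9% to 20.9 ± 1.39% (-33.9 points, adjusted p = 0.0088), Lrmda from 70.0 ± 1.04% to 19.15 ± 6.24% (-50.8 points, adjusted p = 0.0054) and Disp1, needed to release Hedgehog ligands, from 36.6 ± 8.00% to 7.45 ± 3.72% (-29.2 points, adjusted p = 0.0068). Slit3, a guidance cue, also rose at a stable element from 29.9 ± 2.06% to 66.5 ± 7.25% (36.6 points, adjusted p = 0.009). The most higher elements lay at Tbx4, Tbx15 and Tanc1 (3 each), then Hand1, Plxnd1, Cped1, Prag1, Slit3, Pex14 and Col4a2 (2 each). Long genes hold more elements and can head such a ranking for that reason alone.

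**Figure D4:**
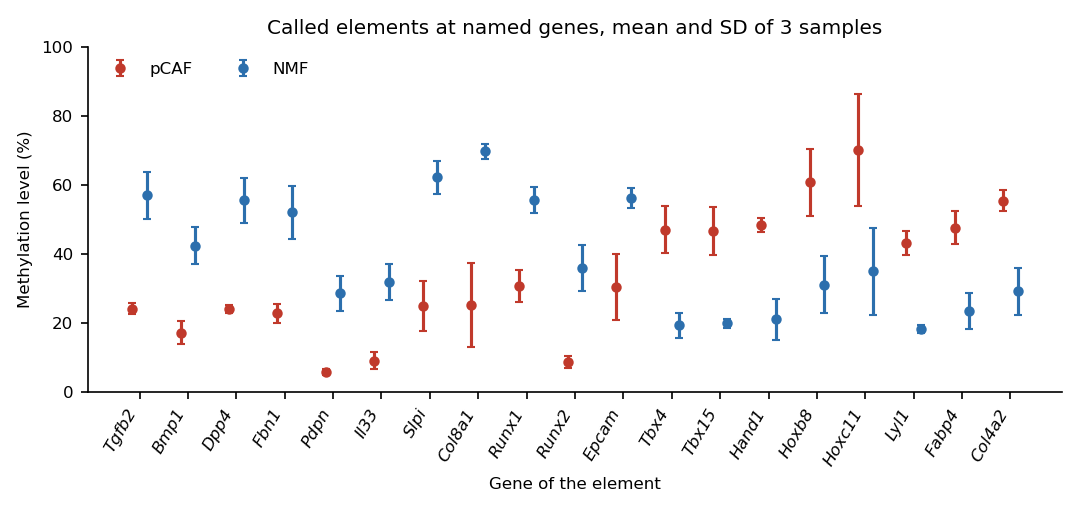
Methylation level (%) of named elements in pCAF and NMF, as mean ± SD of 3 samples per group.

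Gene ends showed few differences that passed the test. Of 65283 ends, 3 rose and 3 fell in pCAF, in all 3 samples each; limma called 0 with no variance trend, and 0 higher and 1 lower with variances of each end alone. The end of Lyl1, a haematopoietic helix-loop-helix factor, rose from 11.7 ± 1.51% to 36.9 ± 2.51% (25.3 points, adjusted p = 0.0034) and overlaps that of Nfix (22.5 points, adjusted p = 0.033), so the 2 are 1 locus, whose element of 100 CpGs was stable (18.3 ± 1.21% to 43.1 ± 3.41%). The end of Hoxa11os, the antisense RNA of Hoxa11, rose from 23.3 ± 1.37% to 63.1 ± 3.33% (39.8 points, adjusted p = 0.0034). The low-coordinate end of Socs3, a feedback inhibitor of cytokine signalling, with 22 CpGs, fell from 44.1 ± 5.21% to 5.98 ± 2.5% (-38.1 points, adjusted p = 0.0065), while its other end differed by -1.36 points (adjusted p = 0.9) and the element of 228 CpGs over the gene by -6.53 points (adjusted p = 0.0061, under the size threshold). The high-coordinate end of Slpi fell from 71.1 ± 1.16% to 40.8 ± 1.68% (-30.3 points, adjusted p = 0.022) and that of Gm41832, a predicted gene named after its value was seen, by 31.0 points (adjusted p = 0.018), a stretch that lies inside the Il33 element. The other ends of Lyl1 (12.5 points, adjusted p = 0.14), Nfix (-3.03 points, 0.82), Hoxa11os (-1.69 points, 0.91) and Slpi (-1.92 points, 0.82) were not called. Without NMF replicate 3 none of the 6 was called (Hoxa11os and Lyl1 0.052, Socs3 0.082, Nfix, Slpi and Gm41832 0.11).

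Other samples mattered for some of these ends. Socs3 was also lost without pCAF replicate 3 (adjusted p = 0.069) or NMF replicate 1 (0.12). Nfix was lost without pCAF replicate 1 (0.074), pCAF replicate 2 (0.054), pCAF replicate 3 (0.2), NMF replicate 1 (0.3) or NMF replicate 2 (0.14). Slpi was lost without pCAF replicate 1 (0.074), pCAF replicate 2 (0.099), pCAF replicate 3 (0.15), NMF replicate 1 (0.29) or NMF replicate 2 (0.1), and Gm41832 likewise (0.074, 0.069, 0.15, 0.27 and 0.072). Among list genes, adjusted over the list alone, the ends of Col1a2 (-23.8 points, adjusted p = 0.03) and Col3a1 (-31.9 points, 0.031), the chains of fibrillar collagens I and III, were lower, as were those of Saa3 (-21.0 points, 0.0027), C3 (-23.4 points, 0.02) and Mfap5 (-20.4 points, 0.026).

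Calls at windows depended on the settings. Of 2036958 windows of 1 kb, 0 were called in either direction by limma (52258 higher and 142999 lower at an unadjusted p under 0.05), while 498063 windows of 5 kb gave 17 higher and 135 lower. The 1 kb counts became 185 higher and 679 lower among windows with at least 10 CpGs, 119 and 501 with untransformed levels and 42 and 185 with the offset 0.1. The 5 kb counts were 21 and 198 without pCAF replicate 1, 15 and 81 without pCAF replicate 2, 16 and 55 without pCAF replicate 3, 11 and 39 without NMF replicate 1, 28 and 186 without NMF replicate 2 and 22 and 64 without NMF replicate 3. On simulated data with changes of 20, 30 and 40 points, 0% of changed 1 kb windows were recovered at each size. The shares were 17%, 60% and 74% for 5 kb windows and 0%, 13.5% and 31.5% for elements. Only a small part of the simulated regions was changed, whereas 28497 of 131383 real elements had an unadjusted limma p under 0.05. The Benjamini-Hochberg adjustment depends on that part, so these shares do not give the power on the real data.

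Of the single CpGs, 26962 rose and 30964 fell, and with the replicate block limma's moderated test, computed in numpy, called 0 in either direction (472219 higher and 618934 lower at an unadjusted p under 0.05). Left-out samples moved the single-CpG counts: without pCAF replicate 1 they were 26989 higher and 56271 lower, without pCAF replicate 2 25649 and 55604, without pCAF replicate 3 44578 and 68663, without NMF replicate 1 64776 and 51943, without NMF replicate 2 66572 and 52267, and without NMF replicate 3 68806 and 44922. The highest of the splits that mix the groups gave 43104 calls in both directions together, against 57926 for the real split. Large counts of single CpGs thus also arise when the groups are mixed. The single-CpG counts were not used to name genes.

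The share of CpGs with a value was alike along the chromosomes of both groups. The X chromosome differed most, where the relative share in pCAF differed from NMF by -0.0106 on the log2 scale, and the next chromosome by -0.00284. Over 526 bins of 5 Mb, the largest chromosome shift in the share was 0.029 in a pCAF sample and 0.0176 in an NMF sample. Read depth itself was not analysed here, so this is a weak test of copy number.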

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

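The alternatives on offsets, untransformed levels, variance trends, element limits and minimum numbers of CpGs were chosen after the data had been examined. So were centring of gene ends and elements, protein-coding genes, camera at elements and all alternatives on elements. At gene ends, the larger size threshold, autosomes alone and variances of each end alone were also chosen then. The same holds for each sample's own CpGs and for means and medians over windows. The others were chosen before the data were examined. Of 1377 values over the tests, named genes and alternatives, 931 kept their direction, side of the threshold or size and 2 reversed. The 1377 include the main values themselves, which can neither keep nor reverse. Some of the 931 could not move, such as level differences with the replicate block. The cause was not tested where a result moved, unless it follows from the setting.

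The genome-wide difference of -1.75 points held its sign throughout: it was -2.01 to -1.43 with each sample left out, -1.80 on each sample's own CpGs, -2.18 as a mean and -2.21 as a median over 1 kb windows. CpG-dense windows turned from 0.182 to -0.642 points on each sample's own CpGs. Numbers of 1 kb windows higher and lower, 0 and 0 in limma, became 42 and 185 with the offset 0.1, 119 and 501 untransformed, 0 and 1 with variances of each window alone, 4 and 1 after centring, 185 and 679 with at least 10 CpGs, 5 and 2 with at least 20 CpGs, 17 and 135 at 5 kb, and 1 and 3 on each sample's own CpGs. They stayed at 0 at 500 bases, 10 or 30 points, the offset 0.01, other variance trends, autosomes, the replicate block and each sample left out.

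Gene ends, 3 higher and 3 lower in limma, became 1 higher at 30 points, 9 and 12 with the offset 0.1, 9 and 14 untransformed, 0 and 0 with no variance trend (2220 and 5012 at an unadjusted p under 0.05), 0 and 1 with variances of each end alone, 17 and 11 after centring, 6 and 10 on autosomes, 0 and 0 at 200 bases to either side, and 9 and 16 with 2000 bases outside. With each sample left out they were 0 to 2 higher and 0 to 2 lower, and 1 was lower with the replicate block.

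Elements, 487 higher and 3257 lower, became 5314 lower at 10 points, 88 and 671 at 30 points, 2099 lower after centring, and 49 and 308 with at least 20 CpGs. Limits of 50% gave 194 higher with 5 CpGs and 210 with 8, and a limit of 40% with 5 CpGs gave 38 and 1121. With variances of each element alone limma called 0 and 0 (4492 and 17291 at an unadjusted p under 0.05). Leaving out each sample gave 38 to 519 higher and 454 to 4340 lower, and the replicate block 586 and 3840. Of 73 named elements and gene ends, 37 stayed on the same side of the calling thresholds without pCAF replicate 3, and none reversed. The numbers were 28 without NMF replicate 1, 34 without NMF replicate 3 and 68 with the replicate block. They include the elements of Runx3, Cbfb, Ptprc and Acta2, which were not called in any of these settings, so fewer calls were kept than these numbers. Single CpGs gave 0 and 0 with the replicate block, and 25649 to 68806 higher and 44922 to 68663 lower with each sample left out.

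Lists by camera, 3 at gene ends and 8 at elements, became 0 and 0 with an estimated correlation, also beside the replicate block, and 1 at 200 bases to either side of gene ends. With each sample left out they were 2 to 4 and 7 to 9. Lists exceeding random ones, 3, became 6 when unmatched (adding adventitial and matrix genes lower and adipocyte genes higher), 1 at 30 points and 1 to 3 with each sample left out. Among the places of called elements, restricting called and tested elements alike by NMF level moved several ratios. Those of lower elements became 0.928 at gene ends, 0.814 between genes and 1.07 (reversed) at CpG-dense elements. Those of higher ones became 0.885 between genes and 0.371 on the X chromosome. At 30 points the last 2 were 0.833 and 0. The coverage by chromosome and by 5 Mb bin (largest difference -0.0106, on the X chromosome) kept its sign with each sample left out.

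Same-numbered samples share only a number: their residuals correlated at 0.0933, 0.0292 and 0.0156, other pairs at -0.073 to 0.0531, and pCAF replicate 3 correlated best with NMF replicate 2, so not every sample correlated best with its own number. Where 1 sample of a group is left out, the variance is pooled over the remaining 5, and the pair left is assumed to vary like the other group. Depth limits what can be seen, yet it is unknown here. The read-count minimums, the removal of the CpGs of highest coverage, the quasi-binomial and negative binomial tests, the thinning of reads, the list offset in reads and all motif alternatives were not run, since the tables hold no counts and no genome was at hand.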

Other observations

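The test of gene ends of other endothelial genes and the 2 tests on developmental factors were written before their results were seen, and all other tests in this part were chosen after the result was seen.

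Some elements near Hox and other developmental transcription factor genes were higher in pCAF. A gain shared by all CpG-dense elements of like level would give list elements no excess, yet 11 of 198 CpG-dense list elements were called higher against 1.33 in matched draws, 8.27 times as many (at most 7 in any draw; permutation test, p = 0.0001, the smallest these draws can give). The draws treat elements as independent, although some list elements share a gene or a gene cluster, so this p overstates the evidence. A gain at developmental factors of other lineages was not seen either: of 104 further factors 1 held a higher element (0.962%, against 15.6% of the first list), 0.786 times the mean of 1.27 of random lists (permutation test, p = 0.725). A biological difference between tumour and normal fibroblasts, different sorted cells and any difference in age stay open and untested. The pattern may be specific to factors active in mesenchymal cells, a hypothesis found on these same data. Activity of the factors in such cells was not tested.

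Gene ends of endothelial genes were higher in pCAF, and a candidate source is endothelial cells left in the NMF sort, which a PDPN gate would reduce except for lymphatic ones. In 38 further endothelial genes that share 0 with the first list, the 37 CpG-richer ends tested were higher in pCAF by 5.22 points on average (median 3.36; random lists -0.878; permutation test, p = 0.0001, the smallest possible; 28 of 37 above 0), in line with that source. Elements of these genes ran both ways: 4 of 35 genes held a higher one (Calcrl, Adgrl4, Rasip1 and Ets1) against 0.888 in random lists (permutation p = 0.0109) and 7 a lower one (Tspan18, Palmd, Adgrl4, Stab2, Stab1, Cyyr1 and Hhex) against 4.30 (permutation p = 0.111). These p-values treat genes as independent, and the first list's camera result (adjusted p = 1.91e-05) is lost with an estimated correlation (0.164). The ends of Plvap (81.5% in pCAF, 66.9% in NMF), Tie1 (80.9% and 65.6%) and Cldn5 (36.3% and 28.4%) go with that source, whereas Pecam1 (84.1% and 86.4%), Kdr (a difference of 0.412 points) and Flt1 (-1.01 points) do not. The Flt1 end was low in both groups (2.42% in pCAF and 3.43% in NMF), so it could hardly show such cells. Without strand, any end taken here may not be the promoter. Another candidate is a smaller share of fibroblasts in NMF with every other cell type raised alike. Endothelial ends exceeded pericyte and smooth muscle ends by 4.42 points (permutation test over shuffled gene labels, p = 0.0007). That gap cannot decide, because most pericyte and smooth muscle ends were already low in both groups. The shuffled labels were not matched on level. A change of endothelial methylation within the sorted cells was not tested.

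The genome-wide level was lower in pCAF. Less complete bisulfite conversion in NMF would raise nearly unmethylated DNA most, but elements under 5% differed by -0.102 points (exact p = 0.4), which argues against it as the whole cause. Tumour epithelial cells in the pCAF sort, which the EpCAM gate would remove, could lower the ends of epithelial genes, yet the 30 CpG-richer ends differed by 1.20 points on average (median 0.847; random lists 0.0561; one-sided permutation p for lower = 0.929; 10 below 0), with Epcam at 34.8% in pCAF and 22.8% in NMF. A small share of such cells cannot be told apart from none by this test, because many of these ends are already low in NMF and no profile of 4T1 cells was used here. PDPN selection and DNA input go with the groups and were not tested, and whether the mice differed in age at collection is not known.

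With 3 against 3 samples there are 10 splits, too few for a share under 0.05. The real split and the highest of the others gave 57926 and 43104 single CpGs (1 split of 10 as high), 0 and 0 windows of 1 kb (10 of 10), 152 and 0 windows of 5 kb (1), 6 and 0 gene ends (1), 3744 and 0 elements (1), 3 and 1 lists by camera at gene ends (1) and 8 and 5 lists at elements (1).

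The sample with the PDPN-negative selection label, pCAF replicate 3, lay nearer to the other tumour samples than to the NMF. Of 913 elements called without it, it was nearer to the mean of the other pCAF than to that of the NMF at 839 (91.9%). Of the 913, 859 were also called with all 6 samples. No tumour sample known to be PDPN-negative was at hand for comparison, so these values cannot decide whether its PDPN label is right.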
